A study of Mus musculus with 2 samples.

How the data were processed

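MicroRNA libraries from heart tissue of 2 biological replicates were used, both from female B6CASTF1/J mice aged 14 days, per the labels. The deposited tables hold, for each library, whole-number read counts per gene, which were not normalized. Per the readme deposited with the tables, the counts were made against mm10 with the microRNA genes of GENCODE M21. The adapter trimming, aligner and counter are not given in the sources used here. The tables have 3 columns of counts without a header, and their values show what each holds. All 3 columns have equal totals, the first is unstranded and alone has reads ambiguous between genes, the second has reads on the gene's own strand and the third those on the opposite strand. The own-strand column was used throughout unless strand is named.

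The first 4 lines of each table name no gene and stayed out of library sizes and tests. Of all reads, 13.4% in replicate 1 and 13.3% in replicate 2 were unmapped, 41.1% and 39.9% mapped to several places, 4.33% and 4.30% lay outside microRNA genes, and 0 were ambiguous on the own strand. Reads mapping to several places are counted for no gene in the deposited counts, so genes with near-identical copies can be undercounted by an unknown amount. Hairpin sequences were taken from the transcripts of GENCODE M21, and a gene was marked uncertain where it shares a stretch of 20 bases with another hairpin. Genes that overlap each other on either strand were not compared with one another, and the rest of the genome was not searched for copies. Positions, hosts and exon or intron context come from the same annotation on mm10. A microRNA gene counted as exonic where any annotated exon of its host, from any transcript, overlapped it.

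Levels were expressed as counts scaled to 1000000 reads assigned to genes (CPM), with mean and SD over 2 libraries and an exact 95% Clopper-Pearson interval per library. A gene was called detected with at least 10 reads in both libraries, and a count of 0 was given a floor of 3 reads. Correlations used log2(CPM + 1), with intervals from 1000 resamplings of genes. The common dispersion was estimated with an intercept-only design in edgeR 4.0.16 under R 4.3.3, with 100 resamplings. Differences between libraries were tested for each gene with at least 10 reads in sum by an exact two-sided binomial test, doubling the smaller tail, with the expected share taken from TMM-scaled library sizes, and p-values were Benjamini-Hochberg adjusted with a threshold of 0.05. Log2 differences had 0.5 reads added to each count and fold changes are their antilogs. For a median of a list, 10000 random lists of the same size were drawn from the 20 nearest genes in mean expression of each member. Ratios within a library were set beside a pooled standard error from the differences between libraries over genes with a mean of at least 100 reads. Other work used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

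The groups, tests, 20 lists, 25 pairs, the rule for named genes and the alternative settings listed first below were chosen before the data were examined. Named were the 20 genes with the highest mean CPM, every detected member of a list of 10 or fewer genes and the 5 highest of a longer list, both genes of each pair with both detected, and, among called genes with a mean of at least 100 reads, the 10 most different in each direction, which gave 100 genes. Members of a list or pair with few reads, and genes seen in 1 library alone, are named beside them as chosen after their values were seen. The lists were cardiomyocyte, skeletal muscle only, smooth muscle, endothelial, fibroblast, erythroid, leukocyte, neuronal, liver, pancreas, epithelial, pluripotent cell, testis X cluster, let-7 family, miR-30 family, miR-15/16 family, miR-17-92 and paralog clusters, miR-23-27-24 clusters, Dlk1-Dio3 imprinted cluster and Sfmbt2 cluster families.

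The alternatives were unstranded reads, each replicate alone, other read minimums, other denominators, a pseudocount of 10, no filter, DESeq2 1.42.0 size factors, total counts, a fold of at least 1.5, and edgeR's exact test at a biological coefficient of variation of 0.1. Results without genes that share 20 bases, and the library test without the erythroid list, were added after seeing the data. The test was tested on simulated data with counting error only over 421 genes. It called 57.1% of genes changed 1.5-fold, 82.0% at 2-fold and 92.0% at 4-fold, and 2.25% of unchanged genes. With a biological coefficient of variation of 0.1 added, over 418 genes, it called 28.6% of unchanged genes and edgeR's exact test 0.893%, so a call of the binomial test shows a difference beyond counting error and not beyond a spread of that size.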

Results

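MicroRNAs, the short RNAs that repress messenger RNAs by base pairing, were sequenced from the heart of female F1 hybrid mice of the cross B6CASTF1/J at an age of 14 days. The libraries held RNA of under 30 bases. There was 1 group of 2 biological replicates, so the data describe the uniquely mapped microRNA reads of the young heart and how far the 2 libraries differed, and no condition was compared. A label of replicate 1 names 3 females and that of replicate 2 names a single female; whether replicate 1 was a pool is not stated. A further label gives the age in months, against 14 days in the age field, and the age field was used. Replicate 1 held 12701590 reads and replicate 2 held 7126319. Of these, 5237062 (41.2%) and 3026501 (42.5%) were counted on the own strand of a microRNA gene, and levels are given as counts scaled to 1000000 of these reads (CPM). Values with an SD are means over both libraries (n = 2). With 2 libraries an SD rests on a single difference and measures only the spread between these samples, and p-values of the test between libraries rest on counting error alone. Intervals are exact 95% Clopper-Pearson intervals and, as reads without molecular identifiers are not independent molecules, intervals and floors cover counting error only.

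Among uniquely mapped reads, the counts were led by Mir378a, the let-7 family and Mir126a. Genes with near-identical copies, such as those of Mir1a and Mir133a, can be undercounted to an unknown degree, so this order need not be that of the heart itself. Mir378a, which lies in an intron of the metabolic coactivator gene Ppargc1b (mm10 chromosome 18, 61397835 to 61397900, minus strand), stood at 184074 ± 2148 CPM (SD, n = 2), or 18.4% ± 0.215 of all counted reads. It shares 20 bases with Mir378c. Mirlet7i followed at 119239 ± 15041 CPM, Mirlet7g at 83496 ± 4186 CPM and Mirlet7d at 56496 ± 3066 CPM. Mir126a, an endothelial microRNA that overlaps an annotated exon of Egfl7 (chromosome 2, 26591357 to 26591429, plus strand), reached 53451 ± 14906 CPM. The next ranks were taken by Mir23b at 49754 ± 6024 CPM, Mirlet7b at 44768 ± 7165 CPM, Mir23a at 31142 ± 6021 CPM, Mir143 at 31063 ± 2742 CPM and Mir139 at 29167 ± 8372 CPM. Mir23a and Mir23b share 20 bases with each other.

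Among the other members of the 20 most abundant genes, Mir99a (27029 ± 716 CPM), Mir30d (17950 ± 28.0 CPM) and Mir30a (7341 ± 11.6 CPM) had nearly equal levels in the 2 libraries. Mir22 (17536 ± 16021 CPM) had an SD close to its mean, and Mir99b stood at 11540 ± 7628 CPM. Mir26b, Mir652, Mirlet7e, Mir191 and Mir322 lay between 16184 and 9264 CPM. The most abundant gene took 18.6% of the counted reads of replicate 1 and 18.3% of those of replicate 2. The top 10 took 66.9% and 70.2%, and the top 50 took 93.7% and 94.1%. Of 2202 annotated microRNA genes, 335 had at least 10 reads in both libraries and were called detected, and 1479 had no read in either. A count of 0 allows up to 0.573 CPM in replicate 1 and 0.991 CPM in replicate 2.

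Among lists of the heart's own cell types, the endothelial and smooth muscle lists held the largest shares of counted reads. Neither has a gene that shares 20 bases with another hairpin, against 6 of 9 cardiomyocyte and 6 of 9 fibroblast genes, so the order holds for uniquely mapped reads only. The endothelial list, in effect Mir126a, took 5.35% ± 1.49 of counted reads, 4.29% (interval 4.27 to 4.31) in replicate 1 and 6.40% (6.37 to 6.43) in replicate 2. The smooth muscle list took 3.21% ± 0.251, nearly all of it Mir143, while its cluster partner Mir145a stood at 1043 ± 235 CPM. The fibroblast list took 0.578% ± 0.326, with Mir21a at 3075 ± 2617 CPM, Mir214 at 1736 ± 487 CPM and Mir29a at 852 ± 181 CPM. The leukocyte list took 0.400% ± 0.0212, led by Mir155 at 2105 ± 727 CPM and Mir146 at 1189 ± 250 CPM. The erythroid list took 0.102% in replicate 1 (0.0989 to 0.104) and 0.739% in replicate 2 (0.730 to 0.749), a difference made by Mir451a.

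The cardiomyocyte list took 0.433% ± 0.123 of counted reads, with 5 of its 9 genes detected. Mir499, in an intron of the myosin gene Myh7b (chromosome 2, 155622880 to 155622958), stood at 2984 ± 704 CPM. Mir208a, in an intron of the alpha myosin heavy chain gene Myh6 (chromosome 14, 54949060 to 54949142), stood at 998 ± 506 CPM, and Mir208b, in an intron of the beta myosin heavy chain gene Myh7 (chromosome 14, 54975700 to 54975776), at 308 ± 28.6 CPM. Mir1a-2, a copy of the abundant striated muscle microRNA miR-1, had only 110 and 101 reads (27.2 ± 8.75 CPM), and Mir133a-1 had 16 and 12 reads. Mir1a-1 had 4 and 6 reads, Mir133a-2 had 7 and 1, Mir133b had 6 and 5, and Mir1b had 10 and 0. Of the 9 genes, 6 share 20 bases with another hairpin and are uncertain, since reads mapping to several places were not counted for any gene.

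Broad families and clusters made up much of the other counted reads. The let-7 family took 32.6% ± 1.249 of counted reads with all 12 annotated members of the fixed 14 detected, and the clusters of Mir23, Mir27 and Mir24 took 8.65% ± 0.362. The miR-30 family took 3.02% ± 0.0529, the miR-15/16 family 1.98% ± 0.0272 and the miR-17-92 and paralog clusters 1.32% ± 0.0860. Of these, 6 of 12 let-7 genes and all 6 genes of the Mir23, Mir27 and Mir24 clusters share 20 bases with another hairpin. So do 2 of 7 miR-30, 2 of 11 miR-15/16 and 4 of 15 miR-17-92 and paralog genes. These shares therefore hold for uniquely mapped reads only. In the imprinted Dlk1-Dio3 cluster (chromosome 12, 109563692 to 109747960), 46 of 55 genes were detected, with 15 above 100 CPM, and the cluster took 1.28% ± 0.0179. Its highest genes were Mir127 (4051 ± 659 CPM), Mir379 (1617 ± 159 CPM) and Mir411 (1478 ± 103 CPM), of which Mir411 shares 20 bases with Mir758. Of the 81 genes of the Sfmbt2 cluster families, 79 share 20 bases with another hairpin, 7 were detected, and the families took 0.134% ± 0.0120, with Mir467d highest at 793 ± 121 CPM.

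Lists of other tissues took few of the counted reads. The epithelial list took 0.0590% ± 0.0203, led by Mir200c at 338 ± 57.7 CPM, and the neuronal list took 0.0263% ± 0.0116, with Mir128-1 and Mir128-2 (which share 20 bases) and Mir137 detected. Of the 9 neuronal genes, 8 share 20 bases with another hairpin, among them Mir124a-1, Mir124a-2, Mir124a-3, Mir9-1 and Mir9-2 with 0 reads, so this share does not show that neuronal microRNAs were rare. Mir122, the main liver microRNA, stood at 63.2 ± 10.2 CPM, and the pancreas list took 0.00450% ± 0.00444, mostly Mir375. Mir206, expressed in skeletal muscle, had 41 and 62 reads. The pluripotent cell list took 0.000951% ± 0.000291, and the testis X cluster had 13 and 6 reads over its 19 genes, none of them detected, where 4 of 13 and 6 of 19 genes share 20 bases.

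**Figure D1:**
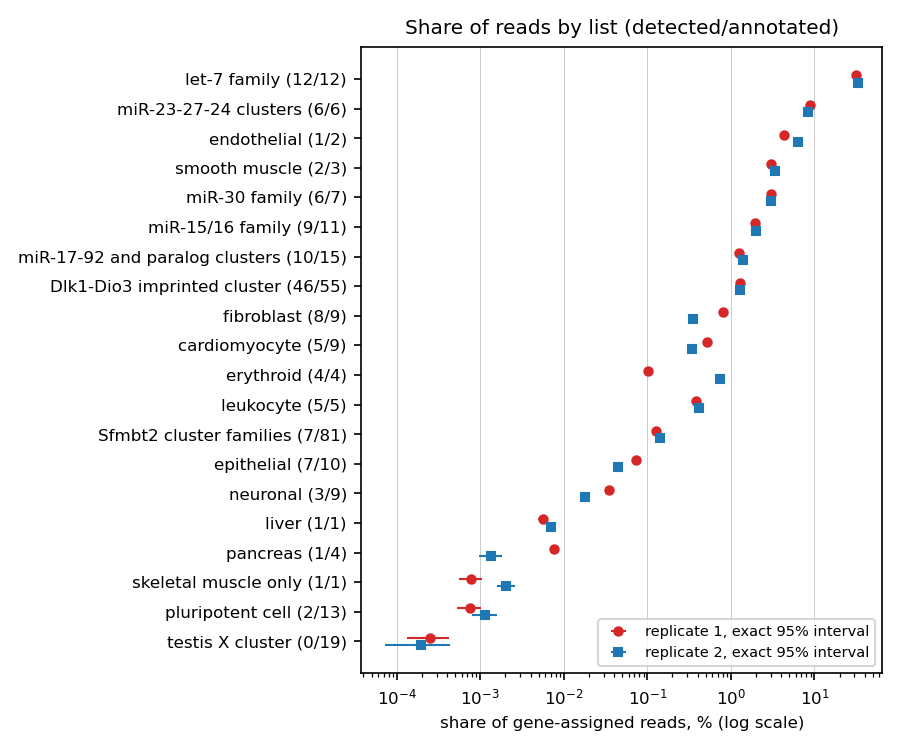
Share of counted reads taken by each of 20 microRNA lists, in percent on a log axis; circles are replicate 1, squares replicate 2, bars exact 95% intervals for counting error, and the figures after each name are detected and annotated genes. The let-7 family lies highest at 31.7% and 33.5%, and the erythroid list shows the widest gap among lists above 0.1%, at 0.102% against 0.739%.

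The 2 libraries ranked the microRNA genes in nearly the same order, yet single genes differed widely. Across the 335 detected genes, Pearson's r of log2(CPM + 1) was 0.970 (95% interval over resampled genes 0.959 to 0.979) and Spearman's rho was 0.961 (0.947 to 0.971). These are correlations across genes, which are not independent replicates. Mir378a, Mir30d and Mir30a lay close to equality, whereas Mir451a, Mir185, Mir22 and Mir26a-2 lay far from it. The SD of the log2 difference was 0.87 (0.74 to 0.99), and the common biological coefficient of variation from edgeR was 0.424 (0.383 to 0.465) over 430 genes with at least 10 reads in sum. Over the 226 genes with a mean of at least 100 reads, the median difference between libraries was 1.32-fold, and 41 genes differed by more than 2-fold.

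**Figure D2:**
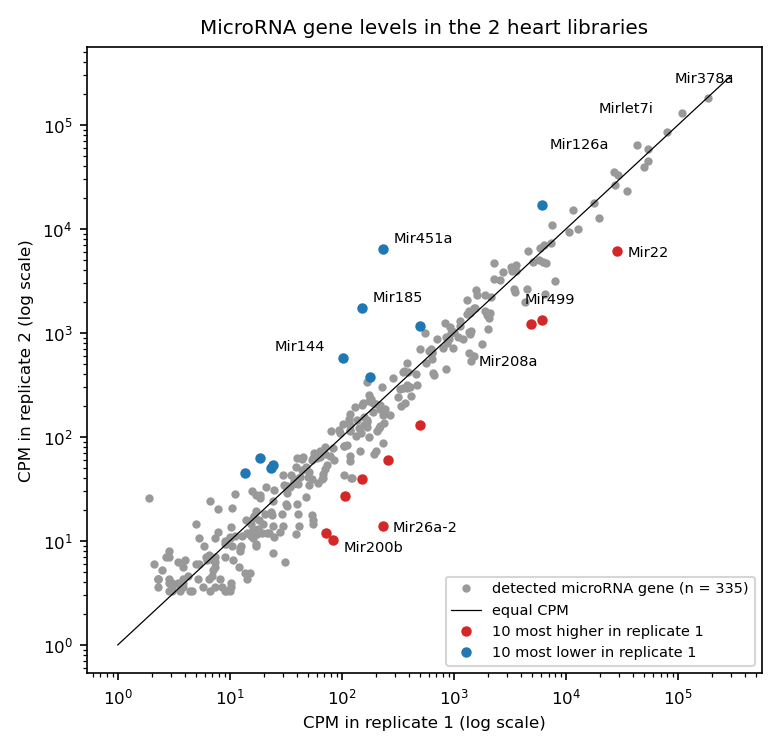
Level of each of the 335 detected microRNA genes in replicate 1 (x) and replicate 2 (y), in CPM on log axes; the line marks equal CPM, and red and blue points are the 10 genes most higher and the 10 most lower in replicate 1 among called genes with a mean of at least 100 reads. Mir378a lies on the line at 184074 CPM, and Mir451a lies farthest above it, at 234 against 6393 CPM.

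Among genes with a mean of at least 100 reads, Mir451a separated the libraries most, and differences between libraries are given after TMM scaling. Mir451a, which is abundant in the erythroid lineage (chromosome 11, 78073170 to 78073241), was lower in replicate 1 by 30.0-fold (1223 against 19348 reads, log2 difference -4.91, counting interval -4.99 to -4.83). Mir144 of the same cluster was lower by 6.15-fold (log2 -2.62, -2.76 to -2.48). Mir185, in an intron of Tango2 (chromosome 16, 18327401 to 18327465), was lower by 12.6-fold (794 against 5275 reads, log2 -3.66). Mir505 (log2 -1.91), Mir199b (-1.83), Mir99b (-1.60), Mir181b-2 (-1.37), Mir301 (-1.27), Mir331 (-1.24) and Mirlet7a-2 (-1.23) completed the 10 genes most lower in replicate 1. Of these, Mir199b, Mir181b-2 and Mirlet7a-2 share 20 bases with another hairpin.

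The 10 genes most higher in replicate 1 included several abundant ones. Mir22, which overlaps an annotated exon of Tlcd2, was higher by 4.24-fold (151165 against 18788 reads, log2 2.08, 2.06 to 2.10). Mir140, which overlaps an annotated exon of Wwp2, was higher by 4.12-fold (log2 2.04). Mir21a, a microRNA raised in many fibrotic tissues, was higher by 3.66-fold (log2 1.87). Mir26a-2 was higher by 15.0-fold (1211 against 42 reads, log2 3.91, 3.48 to 4.40) and shares 20 bases with Mir26a-1. The epithelial Mir200b was higher by 7.38-fold (441 against 31 reads, log2 2.88, 2.38 to 3.48), and Mir375, best known from pancreatic islets, by 5.50-fold (381 against 36 reads, log2 2.46, 1.98 to 3.01). Mir449a (log2 1.98), the myeloid Mir223 (1.83), Mir487b (1.82) and Mir181a-2 (1.79) completed this group. Mir487b and Mir181a-2 also share 20 bases with another hairpin.

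**Figure D3:**
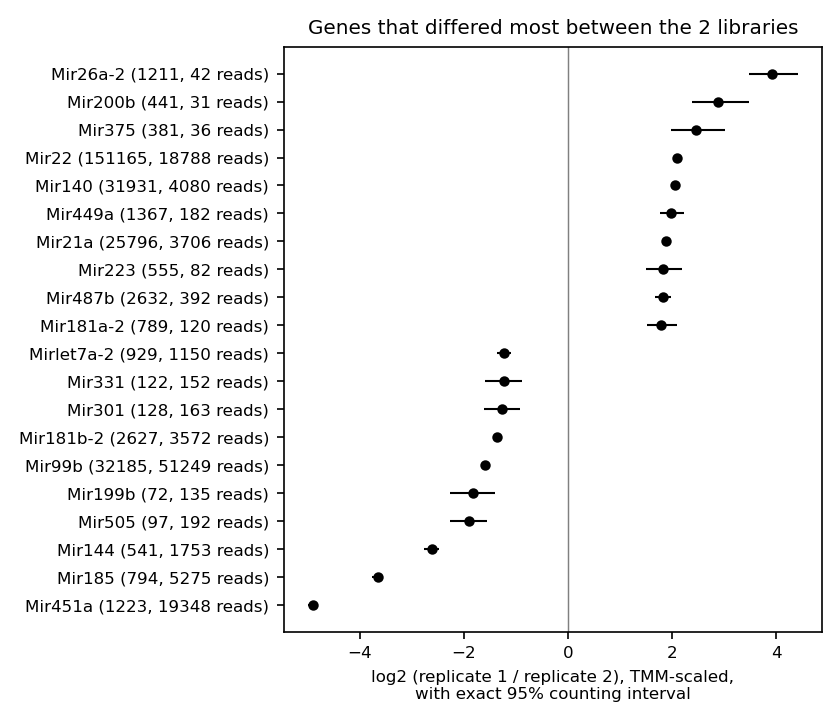
Log2 difference of replicate 1 over replicate 2, scaled by TMM, for the 10 called genes most higher and the 10 most lower in replicate 1 among genes with a mean of at least 100 reads; points are the differences, bars the exact 95% counting intervals, and read counts of replicates 1 and 2 stand after each name. The differences run from -4.91 for Mir451a to 3.91 for Mir26a-2.

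Over all genes, an exact two-sided binomial test with TMM-scaled library sizes and Benjamini-Hochberg adjustment called 238 of 430 genes, 120 higher and 118 lower in replicate 1, and 255 at an unadjusted p under 0.05. It compares these 2 libraries, not conditions. TMM moved log2 differences by -0.13 relative to total counts. With total counts, 240 genes were called, 144 higher and 96 lower, so that 60.0% were higher against 50.4%. Mir378a (log2 -0.11) and Mir99a (log2 -0.08), both called lower with TMM, were called higher with total counts. With edgeR's exact test at a fixed biological coefficient of variation of 0.1, 123 genes were called, but 0.1 lies below the 0.424 estimated from these libraries, so these calls do not show differences beyond the measured spread.

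The fixed lists were compared member by member. Of 9 epithelial microRNAs tested, 7 were higher in replicate 1, among them Mir200b, Mir429 (3.41-fold) and Mir203 (2.19-fold), Mir182 was lower and Mir183 was not called; 8 were called when adjusted over the list alone. The list's median log2 difference of 1.13 lay at the 99.7th percentile of 10000 random lists matched on expression, a description of these libraries. Of the 4 erythroid genes, Mir451a and Mir144 were lower and Mir486 (1.46-fold) and Mir3107 (1.64-fold), which overlap on opposite strands at the Ank1 locus, were higher. All 4 were called when adjusted over the list alone, and the median lay at the 0.350th percentile. Of the clusters of Mir23, Mir27 and Mir24, 5 of 6 genes were higher, with Mir27b by 2.49-fold and Mir27a by 2.41-fold, and Mir23a was lower by 1.45-fold. All 6 were called when adjusted over the list alone, all 6 share 20 bases with another hairpin, and the median lay at the 99.3rd percentile. The medians of the other 10 lists with enough genes for this comparison lay between the 21.8th percentile (miR-30) and the 81.5th (leukocyte). The random lists were drawn gene by gene without regard to locus, while Mir200a, Mir200b and Mir429, Mir451a and Mir144, or Mir27a and Mir23a lie at shared loci, so these percentiles can overstate how unusual a median is.

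Of 8 cardiomyocyte genes tested, Mir208a (1.93-fold) and Mir499 (1.28-fold) were higher in replicate 1, Mir1a-2 was lower by 1.74-fold and 5 were not called, with 3 called when adjusted over the list alone. With total counts 4 were higher, Mir208b among them. Of 8 fibroblast genes, 3 were higher, 3 lower and 2 not called, 6 of them called when adjusted over the list alone. With total counts 4 fibroblast genes were higher and 2 lower, as Mir29b-1 gained a call and Mir29c lost its lower call, the latter also with DESeq2 size factors. Of 5 leukocyte genes, Mir223, Mir150, Mir146 and Mir142 were higher and Mir155 was lower by 1.81-fold, and all 5 were called when adjusted over the list alone. Mir143 was lower by 1.24-fold and Mir145a higher by 1.26-fold, both of them also called when adjusted over the list alone. Mir126a was lower by 1.64-fold, Mir122 by 1.38-fold and Mir206 by 2.86-fold. Each of these was the only tested gene of its list, so adjusting over the list alone adjusts nothing. Of 4 neuronal genes, Mir128-1 and Mir128-2 were higher, Mir137 was lower and 1 was not called, 3 being called when adjusted over the list alone, and Mir137 lost its call with total counts (log2 -0.20). Mir375 was the only one of 2 pancreas genes called, and Mir302d, lower, the only one of 2 pluripotent cell genes called, with 1 in each list when adjusted over the list alone.

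Of 12 let-7 genes, 8 were lower in replicate 1, 3 were higher and 1 was not called, with Mirlet7i lower by 1.31-fold and Mirlet7b higher by 1.14-fold. With total counts, 6 were lower and 3 higher, and adjusted over the list alone 12 were called. All 6 tested miR-30 genes were lower, from 1.10-fold for Mir30d and Mir30a to 1.40-fold for Mir30b; 6 were called when adjusted over the list alone, and 4 of 6 with total counts, where Mir30d (log2 0.0032) and Mir30a (log2 -0.0032) lost the call. Of 9 miR-15/16 genes, 4 were higher and 5 lower, with Mir195a higher by 2.27-fold and Mir322 lower by 1.61-fold, and all 9 were called when adjusted over the list alone. Mir497 lost its lower call with DESeq2 size factors and with total counts, which left 4 higher, 4 lower and 1 not called. Of 11 genes of the miR-17-92 and paralog clusters, 3 were higher, 3 lower and 5 not called, 6 of them called when adjusted over the list alone, and with total counts 5 were higher and 3 lower. Of 47 Dlk1-Dio3 genes, 17 were higher, 10 lower and 20 not called, with 27 called when adjusted over the list alone and Mir487b higher by 3.53-fold, and with total counts 21 were higher and 10 lower. Of 8 genes of the Sfmbt2 cluster families, 3 were higher, 3 lower and 2 not called, and 6 were called when adjusted over the list alone.

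With edgeR's exact test at a biological coefficient of variation of 0.1, most small differences lost their call. It called 0 of 6 miR-30 genes, 2 of 12 let-7 genes, 4 of 9 miR-15/16 genes, 2 of 11 genes of the miR-17-92 and paralog clusters, 14 of 47 Dlk1-Dio3 genes and 3 of 8 genes of the Sfmbt2 cluster families. It called 6 of 9 epithelial genes, 3 of 4 erythroid genes and 5 of 6 genes of the Mir23, Mir27 and Mir24 clusters. It also called 3 of 8 cardiomyocyte, 3 of 8 fibroblast, 3 of 5 leukocyte and 2 of 4 neuronal genes. The 3 cardiomyocyte genes were not all those of the binomial test, as Mir499 lost its call and Mir1b, with 10 and 0 reads, gained one. Mir126a, Mir206, Mir375 and Mir302d kept their calls, and Mir143, Mir145a and Mir122 lost theirs. The call of Mir302d was marginal, with 15 and 21 reads and an adjusted p of 0.0491 by edgeR's exact test.

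Ratios of microRNAs within a library compared genes of shared loci and the myosin-hosted genes. Mir208a exceeded Mir208b by 3.03-fold (log2 1.60 ± 0.63, SD, n = 2), with 2.04 in replicate 1 and 1.15 in replicate 2, and Mir499 exceeded Mir208a by 3.16-fold (log2 1.66 ± 0.42). Mir143 exceeded Mir145a by 30.1-fold (4.91 ± 0.46), Mir322 exceeded Mir503 by 43.0-fold (5.43 ± 0.65), Mir30d exceeded Mir30b by 91.8-fold (6.52 ± 0.25) and Mir221 exceeded Mir222 by 29.8-fold (4.89 ± 0.57). Mir451a exceeded Mir144 by 5.00-fold (2.32 ± 1.62), the least even of the 20 ratios between libraries. Mir30e exceeded Mir30c-1 by 8.95-fold (3.16 ± 0.08), the most even, although Mir30c-1 shares bases with Mir30c-2.

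The ratios of some neighbours changed sign between the libraries. Mirlet7e and Mir99b, both within introns of Spaca6 on chromosome 17, had a log2 ratio of 1.06 in replicate 1 and -0.75 in replicate 2, and Mir195a and Mir497 of 0.74 and -0.53, so neither had a direction. Of 25 pairs fixed beforehand, 20 had both genes detected, and 16 of these ratios exceeded 2 times the pooled standard error of 0.64 on the log2 scale. In 9 of the 16 at least 1 gene shares 20 bases with another hairpin, so the size of those ratios is uncertain. The other 4 were these 2 pairs, Mir17 to Mir92-1 (1.17 ± 0.67) and Mir182 to Mir183 (-0.56 ± 0.61). The pooled standard error rests on differences between the 2 libraries, so it leaves out any bias common to both. It was taken over genes with a mean of at least 100 reads. Among the 16 ratios, those with Mir133a-1 (16 and 12 reads), Mir199a-2 (21 and 20), Mir29b-1 (101 and 36) and Mir29b-2 (15 and 24) include a gene below that mean. It need not cover the spread of these ratios. The size of each of the 20 ratios is open to such a bias. With 2 libraries the exact sign-flip test cannot give a two-sided p below 0.5. Mir126b, the annotated gene opposite Mir126a, had 3 and 0 reads against 224728 and 193669.

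Strand separated overlapping microRNA genes. Among the 2138 genes with no microRNA annotated on the other strand, 99.997% of reads in both libraries lay on the gene's own strand. The other 64 genes held 25.9% and 27.9% of counted reads, among them Mir378a, Mir126a, Mirlet7e and Mir191. When strand was ignored, Mir378a, Mirlet7e, Mir191 and Mir451a had 0 reads and Mir126a had 30 and 8, because their reads became ambiguous between 2 genes. Of all genes, 1087 share 20 bases with another hairpin, and 76 of these were detected.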

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

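Except for the test of GC content as a source, the tests in this part, its use against counting error included, were chosen after the results they bear on were seen. Reads outside the gene counts were seen in both libraries. Reads mapped to several places numbered 5217056 in replicate 1 and 2845614 in replicate 2. Uniquely mapped reads outside microRNA genes numbered 549737 and 306136. On the opposite strand of genes with no microRNA annotated there lay 128 and 56 reads, led by Mir122 with 39 and 28 and Mirlet7b with 17 and 5. They are listed because each lies above the 3 reads that a count of 0 allows, a low bar that tests nothing further, and the 2 samples include no control library.

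The copies of Mir1a and Mir133a had few reads for a heart. Little heart muscle in the samples stays open, since the myosin-hosted Mir208a, Mir208b and Mir499, which have no shared stretch, all lay at or above the 67.5th percentile of detected genes in both libraries, but no other heart sample is at hand to give their usual rank. A candidate explanation is that reads shared between near-identical copies were not counted. In 12 other families with both kinds of member, those sharing 20 bases had lower levels in 9, with a median log2 difference of -3.23. The mean log2 difference was -2.64 (two-sided sign-flip permutation p = 0.0440 for the mean). The family of Mir378, whose sharing members include Mir378a, the most abundant gene, went the other way (log2 5.88). Different genes of a family are compared here, so the test does not show whether any single count lost reads.

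The libraries differed at many genes, and 106 of 113 genes (93.8%) with a mean of at least 1000 reads were called. Counting error, which falls on each gene alone, is argued against as the whole source. Over these 113 genes the median difference was 1.30-fold, while counting reads alone gives a median SD of 0.0274 for the log2 difference. The log2 difference was also related to GC content of the hairpin over 226 genes (Spearman's rho 0.207, Pearson's r 0.145). The permutation p for rho was 0.00160, and 0.00480 when adjusted over the 3 relations tested. GC content itself stays open, as this rho lies below the size of 0.3 set beforehand. The next 2 sources stay open too. The pair correlation for the first rested on Mir451a and Mir144, and that for the second fell without pairs that share a stretch. Real differences between animals were not tested and also stay open. A difference in transcription of the host loci would make neighbours move together, and across 131 pairs of neighbours within 10 kb the pair correlation of log2 differences was 0.142 (permutation p = 0.0472, adjusted 0.0472), but 0.0174 (p = 0.356) without the pair of Mir451a and Mir144, and it was 0.396 (p = 0.0081) over the 49 pairs off chromosome 12, but 0.0650 (p = 0.274) over the 48 of these without erythroid genes. A difference that goes with the microRNA sequence, in the tissue or in library preparation, gave 0.183 over 114 pairs of 1 family. The permutation p was 0.0296, and 0.0444 adjusted. Pairs within 10 kb on 1 strand were left out, yet some of the 114, such as Mir467c and Mir467e in Sfmbt2, lie in 1 host gene. Over the 29 pairs with no shared stretch it was 0.0555 (permutation p = 0.301). Those 29 leave out the pairs most alike in sequence, which are also the pairs that can share reads. The drop therefore cannot tell this source from reads shared between copies, and it decides neither way. Many of the 114 are pairs within the let-7 family.

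MicroRNAs typical of other cell types differed between the libraries. The median of the epithelial list lay at the 99.68th percentile of random lists, drawn without regard to locus, with 7 of 9 genes higher, which is the pattern itself, so RNA of another tissue in replicate 1 stays open and cannot be told apart from other sources. The most abundant member, Mir200c, differed by only 1.16-fold after TMM scaling (1983 against 899 reads), and Mir182 was lower, so a source would need to be rich in Mir200b and Mir205 (172 against 7 reads). More red cell RNA in replicate 2 may explain Mir451a and Mir144, the only 2 of the 4 erythroid list members lower in replicate 1. The others, Mir486 and Mir3107, overlap on opposite strands of 1 locus and are not 2 separate cases. They were not checked for a stretch shared between them. Mir486, made in red cells and in muscle, was higher by 1.46-fold, so this source stays open. No biological difference between groups could be tested, as the design holds a single group.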

How the results depend on the processing

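Results without genes that share 20 bases, and the library test without the erythroid list, were chosen after the data were seen. No paired analysis was possible because there is only 1 group. Apart from 120 shares and ratios of each replicate alone, 745 results stayed on their side of the threshold or moved by less than the spread between replicates, 126 moved further, 105 became weaker, 4 stronger and 10 reversed. With total counts the log2 differences of Mir378a (0.0238), Mir99a (0.0540), Mir382 (0.11), Mir497 (0.0396) and Mir30d (0.0032) reversed, the first 3 of them called, and with no filter on low counts those of Mir378a (0.0189), Mir99a (0.0492), Mir382 (0.10) and Mir497 (0.0348), where Mir497 was again not called. On unstranded reads Mir126a, left with 30 and 8 reads, reversed to 0.94 and was not called. Of 100 named genes tested, 45 lost their call with edgeR's exact test and 47 with a fold of at least 1.5. The 238 called genes became 138 with a fold of at least 1.5 as well, which is stricter by construction. With edgeR's exact test 123 were called, among them Mir1b (10 and 0 reads), which the binomial test did not call. Elsewhere the number ranged from 181 to 240, with 216 on unstranded reads, 234 without the erythroid list and 181 of 340 without sharing genes. With no filter on low counts, Pearson's r became 0.986, Spearman's rho 0.865 and the SD of log2 differences 0.46, as most genes then added have no reads; with a pseudocount of 10 the SD became 0.72. The 335 detected genes became 527 at a minimum of 1 read and 206 at 100 reads. Shares moved with the denominator by construction. The cardiomyocyte share became 0.586% on unstranded reads, 0.180% of all reads and 0.610% without sharing genes. The smooth muscle share became 4.40%, 1.34% and 4.56% under these settings, and 3.93% without Mir378a in the denominator. The endothelial share became 0.000570%, as Mir126a lost its reads, 2.24% and 7.58%. The let-7 share became 43.0%, 13.6% and 45.1%, and 39.9% without Mir378a. The erythroid share fell to 0.0471% on unstranded reads, where Mir451a lost its reads. Each replicate alone lies within 1 SD of a mean of 2 by construction, so that check is void for shares and ratios, yet the log2 ratios of Mirlet7e to Mir99b (-0.75) and of Mir195a to Mir497 (-0.53) changed sign without replicate 1. Depth limits small differences, as on simulated counts 57.1% of genes changed 1.5-fold were called.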

Other observations

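The test of genes with Gm names was written before its result was seen, and the genes of the first paragraph were chosen after their values were seen. Mir99b, Mirlet7e and Mir125a are annotated close together on chromosome 17, and their log2 differences of replicate 1 over replicate 2 were -1.60, 0.21 and 1.20. Mir125a had 42002 and 9597 reads, and Mir99b 32185 and 51249. Mir34c (1013 against 207 reads, log2 1.36) and Mir34b (28 against 0 reads) were higher in replicate 1, as was Mir449a of a related family, while Mir34a was lower (log2 -0.54). Besides Mir34b, the genes with at least 10 reads in replicate 1 and 0 in replicate 2 were Mir3544 (10 reads) and Mir1b (10 reads), and no gene showed the opposite. Genes within introns of a host held 51.7% and 50.01% of counted reads, genes overlapping an exon 36.5% and 36.3%, and intergenic genes 11.8% and 13.7%.

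Of the 2202 microRNA genes, 1021 carry provisional Gm names, and only 6 of these were detected, with Gm23935 the highest at 15.7 CPM. Reads shared between near-identical annotated copies could account for this if Gm-named genes without a shared stretch were detected as often as other such genes. They were not: 5 of 197 (2.54%) were detected, against 254 of 918 (27.7%) other genes without a shared stretch (two-sided Fisher's exact p = 1.59e-18). Uncounted reads shared between annotated hairpins at different places are therefore argued against as the whole cause. Copies outside annotated microRNA genes were not searched for, so uncounted reads shared with those stay open. Whether such genes are silent in heart or make no microRNA was not tested.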
